A study of Mus musculus with 7 samples.

How the data were processed

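Total RNA was sequenced from 7 cultures of neural cells made from mouse embryonic stem cells, with 1 library for each of control, chlorpyrifos, DDT, rotenone, carbaryl, deltamethrin and imidacloprid. Per the labels' protocols, stem cells of the B6G-2 line formed embryoid bodies for 6 days, neural progenitors were grown with bFGF and EGF, and day 14 progenitors were moved to a differentiation medium and exposed for 1 day. The labels used here give no dose and no vehicle, and they name the tissue as brain although the cells were derived from stem cells. The labels name no batch. Groups were taken from the sample titles, and no sample was left out.

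Per the submitters' processing notes, the reads were handled with bcl2fastq 2.17.1.14, cutadapt 1.9.1 and HISAT2 2.0.1 on the mouse build GRCm38. The tool that made the deposited FPKM values is not given in the sources used here. Each deposited file lists FPKM (fragment counts scaled to transcript length and library size) per transcript-structure event, per the file headers. An event is a transcript start, a transcript end, a skipped exon, a retained intron or an alternative exon, and only events with a value above 0 are listed. The authors' FPKM values were used as deposited, with no further scaling.

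The design fixed before the data were examined assumed a table of genes, which these files are not, so gene values had to be built. Start and end events were matched to the GENCODE M21 annotation of the same build, GRCm38, by the inner boundary of the first or last exon. A total of 95.3% of start events and 95.6% of end events matched exactly 1 gene, and they held 96.9% and 96.8% of the start and end FPKM. Repeated lines, between 5388 and 5620 per library, were dropped. Of the matched FPKM, 6.57% stood on a line that names another gene, and the annotation's name was used. A gene's start total and its end total, each summed over events, should both equal its expression, so their difference measures how well a gene was resolved. Genes were kept where the 2 totals, averaged over the 7 libraries, differed by at most 0.3 on the log2 scale, and the mean of the 2 totals was the gene's value. This left 7116 genes, of which 6171 had a mean of at least 1 FPKM over the 7 libraries and entered the comparisons. Another 1791 genes at that level had ends that disagreed, 2511 had a start total only and 260 an end total only, where an end under 5% of the other counted as missing. For these genes the larger end total is given as a value, without a fold. Genes with a single exon have no such event and were not analysed here. The agreement filter was chosen after the data had been seen. Both it and the larger end of every gene had been compared by then, including their top genes and counts, and it was chosen because folds from the 2 ends correlated across genes at 0.74 to 0.77 where the ends agreed and at 0.07 to 0.15 where they disagreed.

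Folds are differences of log2(FPKM + 1), so the pseudocount was 1 FPKM and the change of low genes is understated. With 1 library per group, no difference has a replicate check and no p-value across genes is given. Counts are of genes at 2-fold or more. The same count and the SD of the log2 ratios were taken for all 21 pairs of libraries. No fold is given for a gene listed at 0 in either library. No counts of reads are in the files used and the lowest listed value was 1e-06 FPKM, so the values are estimates that are not whole reads, the depth per library is unknown, and no interval or floor is given.

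For 39 gene lists fixed before the data were examined, the median log2 fold was compared with 10000 random lists of the same size, drawn from genes of like mean log2 FPKM in 50 bins. A median under percentile 0.5 or over percentile 99.5 is said to stand apart, which describes these libraries and is no test of the insecticides. Of the lists, 22 had at least 5 members among the 6171 genes, and the other 17 are given as single values. Counts of members below are of those that could be used, not of the whole list. For the genes on any list, 244 were used, 81 were under 1 FPKM, 58 had ends that disagreed, 56 had a start total only, 11 an end total only and 136 matched no start or end event. The last group includes every mitochondrially encoded gene. List medians between exposed libraries were added after the data had been seen. Counts of genes past the threshold in several comparisons were set against 100 shuffles of each gene's values over the 7 libraries.

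The named genes follow a rule fixed before the data were examined. In each comparison they are the 8 highest and 8 lowest folds at 2-fold or more among genes with a mean of at least 5 FPKM, leaving out predicted models, clone names and pseudogenes. To these come fixed markers of glia, neurons and progenitors, and up to 4 members with the largest absolute fold of each list described. Some genes that this rule names are not reported here.

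The steps were tested on simulated data. From an event table made from the annotation for 2000 genes, 1945 had ends that agreed and 1934 of these returned their true value within 1e-06 on the log2 scale. These events had no noise and the same transcript shares in all 7 libraries. They thus tested the matching, not reads divided differently among transcripts from library to library. Values made from the control library alone, with a noise SD of 0.1 on the log2 scale, stood in for chlorpyrifos against control. Of 6171 genes, 200 at 5 FPKM or more in control were changed. Then 187 of 200 were called at a simulated fold of 2.5, 200 of 200 at 4 and 0 of 200 at 1.5. There were 0 unchanged genes called, but log2 ratios of real pairs had an SD of 0.31 to 0.35. The count of 0 thus does not carry over to these libraries. On the real folds of chlorpyrifos against control, 1.2% of 500 random lists of 12 genes stood apart, and all 100 lists shifted by 0.4 did. The shift was equal for every member. Every list median against control that stood apart below, except the integrated stress response with DDT, was smaller in size than 0.4. Finding shifts of such size, or shifts uneven across members, was thus not tested.

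The alternatives planned beforehand were a pseudocount of 0.1 FPKM, no filter or a filter at 5 FPKM, rescaling by the median of ratios or to a common larger sum per library, the median of the 6 other libraries as reference, protein-coding genes alone, a threshold of 1.5-fold, and random lists not matched on expression. Added after the data were seen were the larger end of every gene, either end total alone over the same 6171 genes, and genes with 1 annotated transcript. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.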

Results

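RNA was sequenced from neural cells made from mouse embryonic stem cells and exposed to an insecticide for 1 day while they differentiated. The stated purpose was to find how insecticides disturb the developing nervous system, with glial differentiation in the series title. There were 7 libraries, with 1 each for control, chlorpyrifos, DDT, rotenone, carbaryl, deltamethrin and imidacloprid. Each library listed between 90522 and 92229 distinct transcript-structure events with a value in FPKM, and 67938 of 126309 distinct events were listed in all 7. The depth per library is unknown, since the files used give no read counts. With 1 library per group, no difference below has a replicate check. Folds are on the log2(FPKM + 1) scale, insecticide against control, over 6171 genes with a mean of at least 1 FPKM whose transcript starts and ends gave like totals. Positions are on GRCm38.

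Between any 2 of the 7 libraries, about as many genes differed 2-fold as between an insecticide and control. The insecticide libraries each had 106 to 135 genes at 2-fold or more against control, 1.72% to 2.19% of the genes. The 15 pairs of exposed libraries had 111 to 143 such genes, with a median of 119 against a median of 113 for the 6 pairs with control. Chlorpyrifos against carbaryl had the highest count of any pair, 143, and rotenone against control the lowest, 106. The SD of the log2 ratios was 0.31 to 0.34 for pairs with control and 0.32 to 0.35 for exposed pairs. Within 1.5-fold of control were 93.3% to 94.1% of the genes. Among genes of 5 to 20 FPKM, 12.6% of those with at least 5 annotated transcripts (180 of 1429) differed 2-fold in some pair, against 1.03% of those with 1 transcript (2 of 194). Among genes of 1 to 5 FPKM the shares were closer, 16.7% and 9.76%. The 2-fold differences of single genes below therefore cannot be separated from the variation between any 2 libraries. The lists of genes that share a function are given beside them. Several genes recur below. Serinc1 was lower with DDT, carbaryl, deltamethrin and imidacloprid, and Crip2 with carbaryl, deltamethrin and imidacloprid. Rsrc1 was higher with chlorpyrifos, DDT, rotenone, deltamethrin and imidacloprid. A gene given without its range in the other exposed libraries is thus not shown to be particular to that insecticide.

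**Figure D1:**
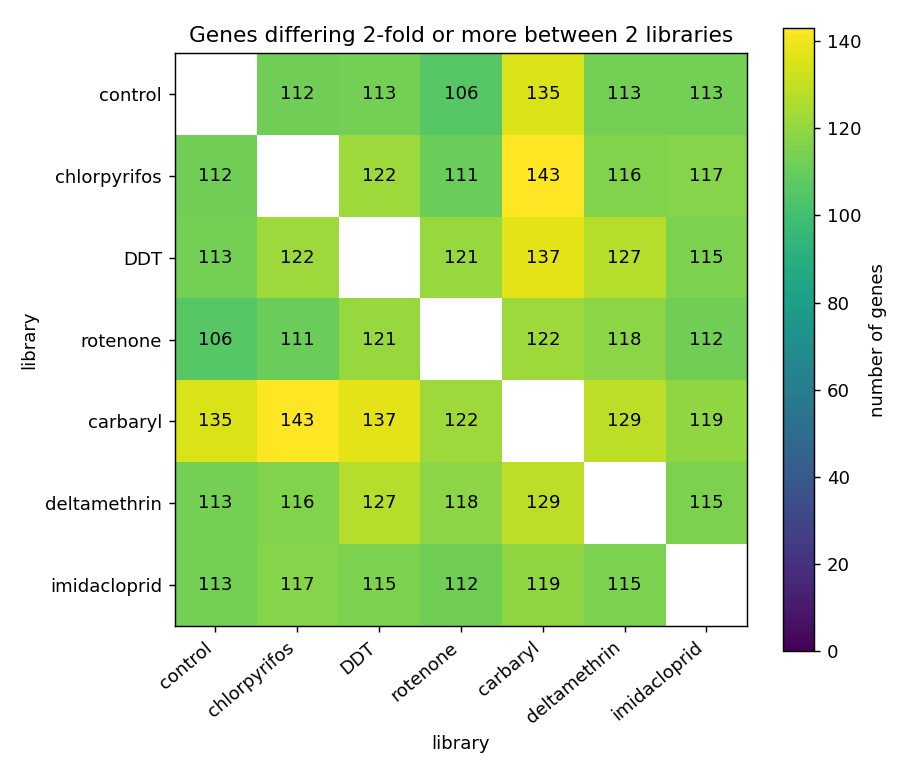
Number of genes differing 2-fold or more on the log2(FPKM + 1) scale between each 2 of the 7 libraries, with the libraries on both axes and the count in each square. The counts run from 106 to 143, with 106 to 135 for pairs with control and 111 to 143 for pairs of exposed libraries.

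DDT, an organochlorine that holds sodium channels open, was compared with control for its effect on developing neural cells, and it had the 2 list medians farthest from 0. Genes of the integrated stress response, the program that ATF4 drives when translation is slowed, were higher, with a median log2 fold of 0.48. Of the 20 genes in this list 11 could be used, and 11 of 11 were higher. Growth factor Gdf15 stood at 6.93 FPKM against 0.895 in control (2.07), and the glutathione-degrading enzyme Chac1 (chromosome 2, 119351229 to 119354381) at 8.49 against 2.10 (1.62). The cystine transporter Slc7a11 was higher at 4.56 against 1.76 (1.01), and the pseudokinase Trib3 at 2.18 against 0.66 (0.94). Genes of cholesterol synthesis were lower, with a median of -0.38 and 12 of 12 usable members lower, of 21 in the list. The sterol oxidase Msmo1 stood at 42.1 against 100.4 (-1.23), Acat2 (chromosome 17, 12942890 to 12960747) at 49.05 against 96.9 (-0.97), the lanosterol synthase Lss (chromosome 10, 76531588 to 76557138) at 15.3 against 27.5 (-0.81), and Hmgcs1 (chromosome 13, 119690379 to 119708260), which makes HMG-CoA, at 180.5 against 253.6 (-0.49). Msmo1 was also low with chlorpyrifos, at 39.5. The stress response median lay at percentile 99.99 of random lists and the cholesterol median at percentile 0. Genes of G2 and mitosis were slightly lower, with a median of -0.16 at percentile 0.04 and 12 of 16 members lower. Among them were cyclin B1 (Ccnb1, 30.3 against 60.3, -0.97), the proliferation marker Mki67 (35.6 against 52.5, -0.55), the spindle factor Tpx2 (39.3 against 53.6, -0.44) and Cdc20 (46.7 against 60.5, -0.37). The unfolded protein response had 12 of 14 members higher with a median of 0.11, which did not stand apart at percentile 97.4. NRF2 targets G6pdx (19.0 against 8.94, 1.01) and Hmox1 (31.0 against 19.8, 0.62) were higher, though their list did not stand apart.

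**Figure D2:**
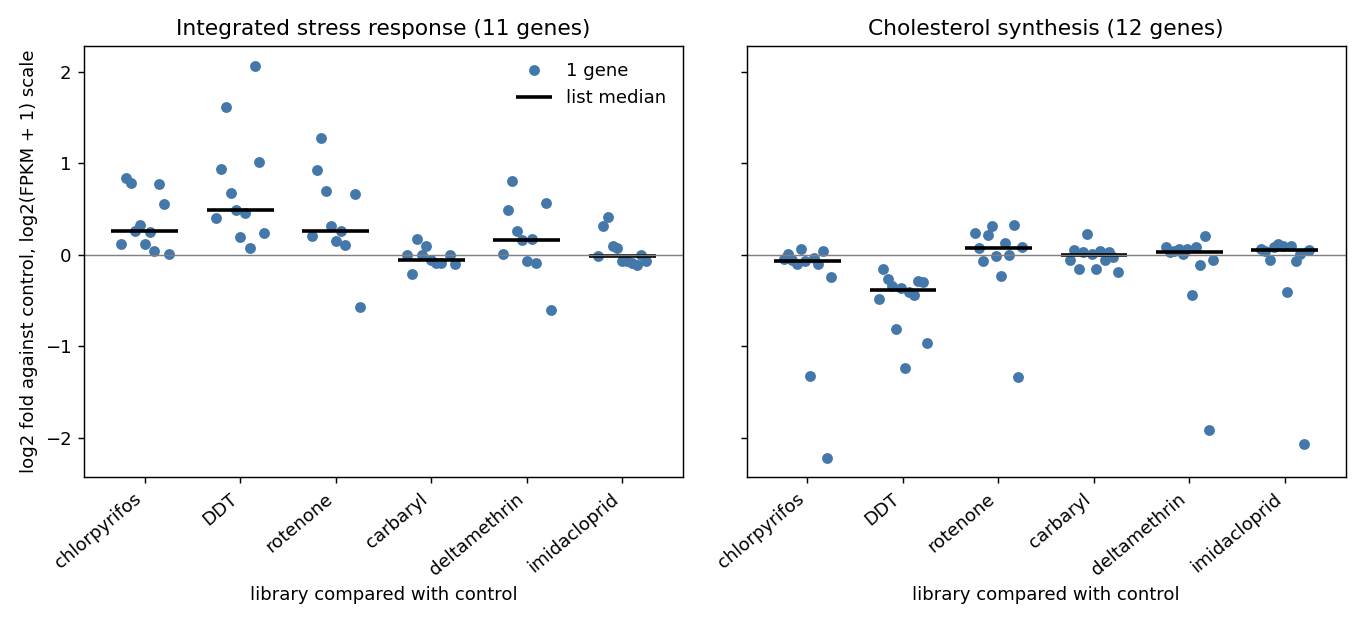
Log2 fold of each member gene (points) and the list median (bars) against control for the integrated stress response (left, 11 genes) and cholesterol synthesis (right, 12 genes), by insecticide on the horizontal axis. A gene not listed with an insecticide, such as Gdf15 with rotenone, carbaryl and deltamethrin, has no point there but counts in the median. With DDT all 11 stress response genes lie above 0 and all 12 cholesterol genes below it, with medians of 0.48 and -0.38.

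Of the single genes with DDT, 52 were 2-fold or more higher and 61 lower. The glucose transporter Slc2a1 (chromosome 4, 119108711 to 119137983) stood at 22.9 against 3.74 FPKM (2.33), Abi2, an actin regulator, at 26.7 against 4.41 (2.36), and the zinc transporter Slc39a7 at 61.6 against 16.2 (1.87). The splicing factors Rsrc1 (13.6 against 2.44, 2.09) and Lsm5 (27.2 against 7.54, 1.72) were higher, as were the magnesium transporter Nipa2 (12.1 against 2.06, 2.10), the spindle-pole gene Mzt2 (17.2 against 3.58, 1.99) and the synaptic vesicle gene Syt1 (12.9 against 3.07, 1.77). The cell cycle inhibitor Cdkn2d (chromosome 9, 21288410 to 21291407) was not listed with DDT against 10.4 in control and 1.97 to 23.8 in the other exposed libraries. The deubiquitinase Josd2 (1.82 against 21.7, -3.01), the mitochondrial import pore Tomm40 (11.2 against 76.8, -2.67), Serinc1 (9.40 against 52.8, -2.37) and the transcription factor Nfya (4.78 against 23.7, -2.10) were lower. So were the palmitoyltransferase Zdhhc20 (2.51 against 12.04, -1.90), the receptor Gpr19 (0.902 against 5.83, -1.84) and the chromatin assembly factor Chaf1a (4.90 against 18.4, -1.72). Tomm40 was at 39.5 to 80.2 and Chaf1a at 15.2 to 18.7 in the other 5 exposed libraries, whereas Slc2a1 ranged from 2.96 to 22.2 there.

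Rotenone, an inhibitor of mitochondrial complex I, was compared with control for the effect of blocked respiration, and genes of the dividing cell were slightly lower while genes of the integrated stress response were higher. Genes of S phase had a median of -0.20 (percentile 0.03, 11 of 15 lower), with the ribonucleotide reductase Rrm1 at 43.2 against 57.7 FPKM (-0.41), the replication licensing gene Cdc6 at 10.9 against 14.3 (-0.36) and the helicase subunit Mcm6 at 43.8 against 52.8 (-0.26). Another subunit, Mcm4, was higher at 42.6 against 33.0 (0.36). Rrm1 (42.3 to 46.5) and Cdc6 (9.59 to 12.04) were below control and Mcm4 (42.6 to 47.4) above it in all 6 exposed libraries, and the list's median was -0.13 against the median of the 6 others, where it still stood apart. Genes of G2 and mitosis had a median of -0.17 (percentile 0.06, 15 of 16 lower), with Ccnb1 at 44.3 against 60.3 (-0.44), the kinetochore gene Cenpf at 13.0 against 17.3 (-0.39) and Tpx2 at 43.0 against 53.6 (-0.31). This list stood apart under 8 of 10 other settings, and its median was -0.10 against the median of the 6 other libraries, where it did not. The integrated stress response was higher, with a median of 0.26 (percentile 99.88, 9 of 11 higher), and Chac1 at 6.52 against 2.10 (1.28), Trib3 at 2.14 against 0.66 (0.92) and the asparagine synthetase Asns (chromosome 6, 7675169 to 7693254) at 53.6 against 32.8 (0.69). Gdf15 was not listed with rotenone. Immediate early genes, transcribed within minutes of a stimulus, had a median of 0.30 (percentile 99.68). Of 16 in the list 6 could be used, and 6 of 6 were higher. Fos stood at 4.74 against 2.66 (0.65) and Egr1 at 19.97 against 14.0 (0.49). The list stood apart under 6 of 9 other settings. The nuclear complex I subunits, the target of rotenone, had 15 of 19 members higher with a median of 0.10, which did not stand apart at percentile 97.4. Ndufv1 (38.2 against 24.5) and Ndufa10 (51.4 against 33.2) were higher and Ndufb5 (39.98 against 66.4, -0.72) lower. None was particular to rotenone, since Ndufa10 was at 45.9 to 53.5 in all 6 exposed libraries, Ndufv1 at 48.8 to 63.5 with chlorpyrifos, DDT, carbaryl and imidacloprid, and Ndufb5 at 27.8 with chlorpyrifos. Glycolysis (median 0.09) and the hypoxia response (0.08) did not stand apart. Fibroblast genes such as Acta2 (6.98 against 3.59, 0.80) and Postn (4.14 against 2.31, 0.63) were higher in 9 of 10, with a median of 0.26 at percentile 99.21.

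With rotenone 49 genes were 2-fold or more higher and 57 lower. Eno1b (chromosome 18, 48045335 to 48048412) stood at 86.3 FPKM against 3.33 (4.34), and it was also high with carbaryl (107), deltamethrin (103) and imidacloprid (72.1), but not with chlorpyrifos (2.55) or DDT (5.47). Eno1b is a near copy of the glycolytic enzyme gene Eno1, and whether reads were assigned to the right copy was not tested. The kinesin Kif22, which moves chromosomes, was lower at 1.13 against 22.1 (-3.44), with 20.3 to 23.7 in the other exposed libraries. Josd2 (0.771 against 21.7, -3.68), the ferritin receptor Ncoa4 (3.19 against 23.4, -2.54), Faf2 of protein degradation at the endoplasmic reticulum (3.70 against 15.3, -1.79) and the ribosome maturation factor Eif6 (16.9 against 55.7, -1.67) were lower. So were Brwd1 (5.37 against 19.0, -1.65), the heat shock import factor Hikeshi (5.13 against 18.1, -1.64) and the presynaptic gene Tprgl (12.1 against 38.3, -1.58), which was at 37.8 to 44.5 in the other exposed libraries. Higher were Smim10l1 (11.2 against 0.498, 3.02), Nipa2 (13.3, 2.22), Lgalsl (11.6 against 2.01, 2.06), the helicase Dhx29 (15.5 against 3.05, 2.03), Rsrc1 (12.7 against 2.44), the prostaglandin reductase Ptgr2 (9.24 against 1.69, 1.93) and Mzt2 (14.9, 1.80).

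Chlorpyrifos, an organophosphate that inhibits acetylcholinesterase, was compared with control for the effect of that class, and it had higher stress response genes of moderate size. The integrated stress response had a median of 0.26 (percentile 99.88), with 11 of 11 members higher, and stood apart under 9 of 10 other settings. Among genes of at least 5 FPKM its median was 0.12 and did not stand apart. Trib3 stood at 1.95 against 0.66 FPKM (0.83), Chac1 at 4.33 against 2.10 (0.78), Gdf15 at 2.24 against 0.895 (0.77) and Slc7a11 at 3.05 against 1.76 (0.55). Genes that p53 activates had a median of 0.19 (percentile 99.55, 6 of 8 higher), with the cell cycle inhibitor Cdkn1a at 79.2 against 61.0 (0.37), Ccng1 at 88.4 against 74.3 (0.25) and Plk2 at 37.2 against 31.7 (0.22). The receptor Eda2r of that list was lower, at 2.01 against 5.32 (-1.07), and the list stood apart under 3 of 10 other settings. Of the single genes, 48 were higher and 64 lower. The adaptor Bex1 (chromosome X, 136213972 to 136215513), expressed in brain, stood at 1.32 against 26.4 (-3.56), with 15.4 to 28.8 in the other exposed libraries. The RNA-binding protein gene Tardbp (chromosome 4, 148612382 to 148627019), which encodes TDP-43, stood at 22.4 against 119 (-2.36), with 60.1 to 132 elsewhere. The translation factor Eif4b (24.4 against 89.4, -1.83) was at 85.1 to 92.9 in the other exposed libraries. The tethering factor Vps51 (3.30 against 18.6, -2.19), esterase D (Esd, 10.2 against 46.5, -2.09), the sterol carrier Stard4 (3.64 against 20.5, -2.22), the protein kinase A inhibitor Pkig (6.39 against 30.0, -2.07) and the Notch regulator Dtx2 (1.23 against 7.49, -1.93) were lower. Higher were Smim10l1 (16.2 against 0.498, 3.52), the mitochondrial ribosome gene Mrps24 (47.4 against 9.63, 2.19; at most 18.5 elsewhere), Mzt2 (18.8 against 3.58, 2.12), Rsrc1 (12.5, 1.97), Nipa2 (10.9, 1.96), Dhx29 (14.2, 1.91), Lgalsl (9.24, 1.76) and the deadenylase subunit Cnot3 (26.7 against 7.77, 1.66).

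Carbaryl, a carbamate that also inhibits acetylcholinesterase, was compared with control for the same question, and unlike chlorpyrifos it had no higher stress response. The integrated stress response had a median of -0.06 (percentile 13.2), with 9 of 11 members lower. Of these, Atf4 (101.6), Asns (32.8) and Slc7a11 (1.76) had the same FPKM in control to the digits given, and Gdf15 was not listed with carbaryl. Between the 2 libraries of acetylcholinesterase inhibitors, 143 genes differed 2-fold, and 34 genes passed the threshold the same way in both against control. Immediate early genes had a median of 0.31 (percentile 99.65, 6 of 6 higher), with Nr4a3 at 1.75 against 0.58 FPKM (0.80), Fos at 4.26 against 2.66 (0.52), Egr1 at 18.7 against 14.0 (0.39) and Arc, a synaptic immediate early gene, at 6.40 against 5.34 (0.22). The list stood apart under 6 of 9 other settings, and its median was 0.14 against the median of the 6 other libraries. All 8 of the 8 p53 targets were higher with a median of 0.17, which did not stand apart at percentile 98.96, with Cdkn1a at 75.7 against 61.0 (0.31) and Trp53inp1 at 20.3 against 16.6 (0.27). The ribosomal protein gene Rpl23 stood at 226 against 467 (-1.04), but its list did not stand apart, with a median of -0.03 (percentile 14.0, 5 of 15 higher). Of the single genes, 54 were higher and 81 lower. Kcnk2, a potassium channel, stood at 10.9 against 1.27 (2.39), with 3.46 to 6.59 in the other exposed libraries. Higher too were Abi2 (45.6 against 4.41, 3.11), Lsm5 (32.7 against 7.54, 1.98), Slc39a7 (65.7 against 16.2, 1.96), Smim10l1 (5.41, 2.10), Nipa2 (11.4, 2.02) and Mzt2 (16.5, 1.93). The sterol-sensing receptor Nr1h2 (1.60 against 13.3, -2.46) was at 12.1 to 14.9 in the other exposed libraries, and the phosphatase inhibitor Ppp1r11 (4.06 against 22.5, -2.22) at 19.9 to 23.9. Lower too were Crip2 (9.49 against 71.6, -2.79), Serinc1 (8.52 against 52.8, -2.50), the KIT ligand gene Kitl (12.5 against 62.4, -2.23), Ncoa4 (4.21 against 23.4, -2.23), the noncoding RNA Tug1 (2.34 against 12.9, -2.06) and Dmap1 (3.36 against 16.8, -2.03).

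Deltamethrin, a pyrethroid that like DDT keeps sodium channels open, was compared with control for its effect on developing neural cells, and none of the 22 lists stood apart. NRF2 targets, the antioxidant response, came near with a median of 0.12 (percentile 99.26, 11 of 13 higher), and had G6pdx at 15.1 against 8.94 FPKM (0.70), Hmox1 at 26.1 against 19.8 (0.38), Pir at 3.35 against 2.36 (0.37) and Srxn1 at 14.5 against 11.2 (0.35). Genes of G2 and mitosis had 13 of 16 members lower with a median of -0.10 (percentile 0.82), with the motor Cenpe at 7.80 against 14.6 (-0.82). Oligodendrocyte markers had a median of -0.31 (percentile 1.84, 4 of 5 lower), with the precursor marker Pdgfra at 1.60 against 2.36 (-0.37). Growth cone gene Gap43 stood at 85.4 against 180 (-1.07), the vesicle gene Rab3a at 9.81 against 20.1 (-0.96) and the p53 target Bbc3 at 11.7 against 7.39 (0.60). The neuronal list with Gap43 had a median of -0.03 (4 of 9 higher) and the synaptic list with Rab3a of 0.0004 (4 of 8 higher). The integrated stress response (0.16), p53 targets (0.15) and immediate early genes (0.23) were higher without standing apart. Of the single genes, 48 were higher and 65 lower. The purine synthesis gene Paics stood at 17.7 against 109.9 (-2.57), with 41.9 to 104.5 in the other exposed libraries, and the cilia regulator Foxj1 at 1.69 against 8.07 (-1.75), with 2.96 to 7.80. The receptor chaperone Mesd (7.99 against 31.2, -1.84), Crip2 (8.27 against 71.6, -2.97), Serinc1 (7.82 against 52.8, -2.61), Kitl (12.9 against 62.4, -2.19), Cdkn2d (1.97 against 10.4, -1.94) and Stard4 (4.72 against 20.5, -1.91) were lower. Higher were Smim10l1 (15.2, 3.44), Slc2a1 (22.2 against 3.74, 2.29), Mzt2 (17.9, 2.05), Syt1 (14.7 against 3.07, 1.95), Nipa2 (10.4 against 2.06), Rsrc1 (11.3, 1.84) and Commd6 (16.3 against 3.87, 1.83).

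Imidacloprid, a neonicotinoid that acts on nicotinic acetylcholine receptors, was compared with control for its effect on developing neural cells, and immediate early genes had its largest median, 0.36 (percentile 99.77, 6 of 6 higher). The list stood apart under 5 of 9 other settings, and its median was 0.051 against the median of the 6 other libraries. Egr1 stood at 23.4 against 14.0 FPKM (0.71), Fos at 4.69 against 2.66 (0.64), Nr4a3 at 1.34 against 0.58 (0.56) and Arc at 6.05 against 5.34. The integrated stress response was near control, with a median of -0.01 (percentile 30.0). Progenitor and radial glia markers had a median of 0.11 (percentile 95.04), with the Notch effector Hes1 at 32.7 against 27.0 (0.26), and the neuronal fate gene Neurog2 stood at 1.37 against 0.72 (0.46), with 1.02 to 1.42 in all 6 exposed libraries. The complex I subunit Ndufv1 stood at 63.5 against 24.5 (1.34), and Eda2r (1.47 against 5.32, -1.35), Rpl19 (338 against 723, -1.10) and Ccnb1 (34.5 against 60.3, -0.79) were lower. None of their lists stood apart against control. The complex I subunits with Ndufv1 had a median of 0.07 (13 of 19 higher) and the p53 targets with Eda2r of 0.04 (6 of 8 higher). G2 and mitosis with Ccnb1 had a median of 0.01 (9 of 16 higher). The ribosomal proteins with Rpl19 had a median of -0.01 (7 of 15 higher) at percentile 1.67. Against the median of the 6 others, the ribosomal proteins stood apart as lower (-0.06) and G2 and mitosis as higher (0.13). Of the single genes, 55 were higher and 58 lower. The BMP modulator Twsg1 stood at 22.2 against 5.36 (1.87), and Nipa2 (11.9, 2.07), Mzt2 (17.5, 2.02), Lgalsl (10.4, 1.92), Smim10l1 (4.40, 1.85), Rsrc1 (11.1, 1.82) and Lsm5 (28.2, 1.77) were higher. The ribosome assembly gene Rpf2 stood at 1.92 against 11.0 (-2.03), with 13.2 to 26.7 in the other exposed libraries, and the ubiquitin enzyme Ube2g2 at 5.43 against 24.5 (-1.99), with 22.7 to 26.8. Lower too were Zfp426 (1.84 against 11.4, -2.13), Crip2 (10.1 against 71.6, -2.71), Serinc1 (7.93 against 52.8, -2.59), Dmap1 (3.11 against 16.8, -2.12), Stard4 (4.13 against 20.5, -2.07) and Pkig (7.95 against 30.0, -1.79).

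**Figure D3:**
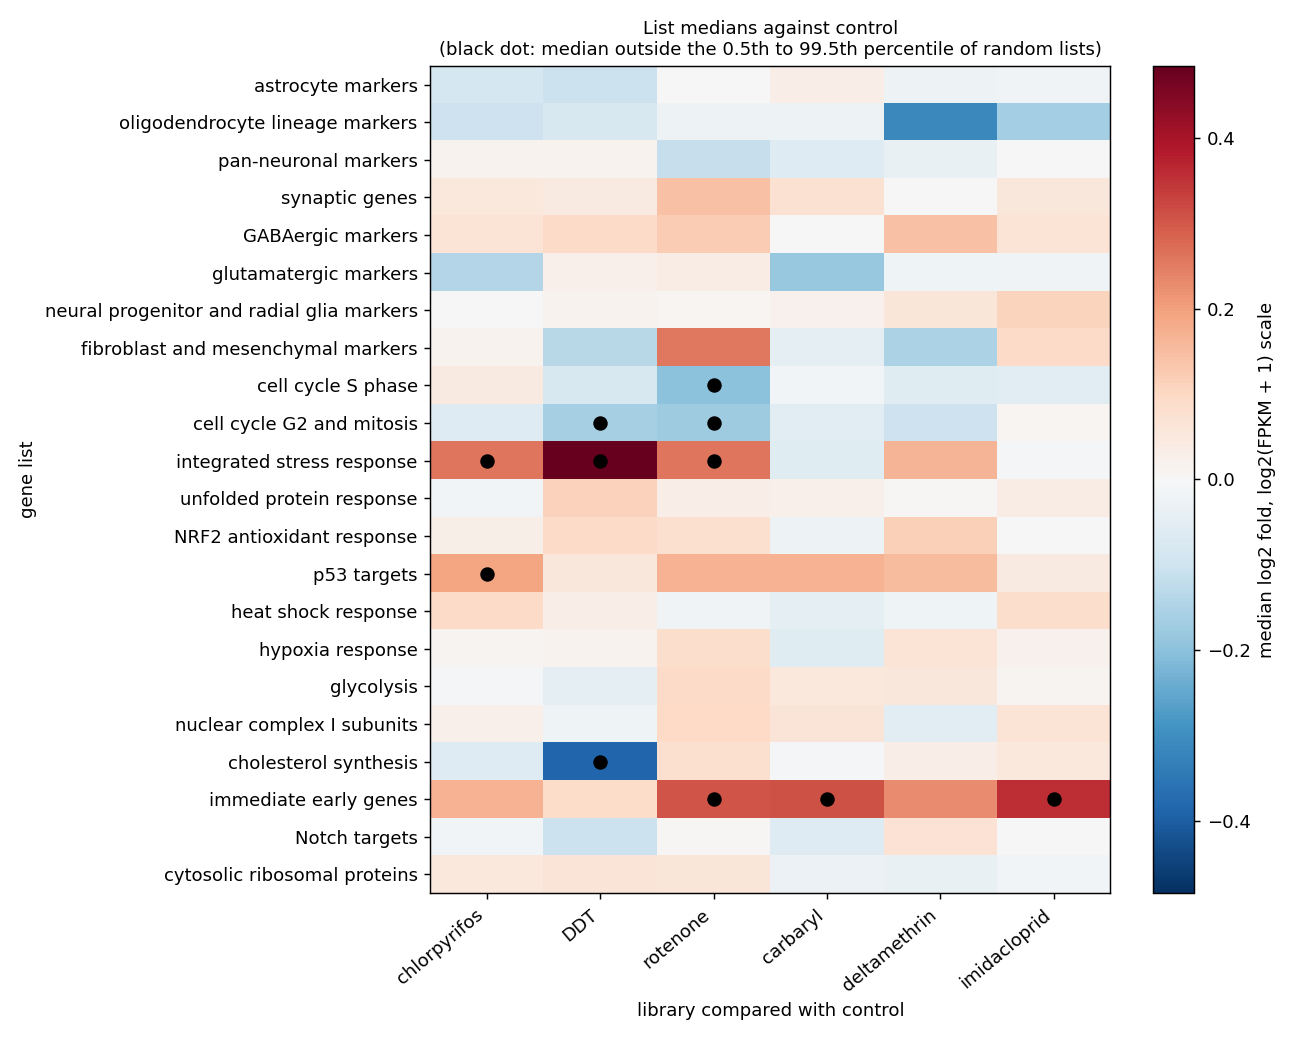
Median log2 fold against control on the log2(FPKM + 1) scale (colour) of the 22 gene lists with at least 5 members (vertical axis) for the 6 insecticides (horizontal axis), with a black dot where the median lay outside all but the outermost 0.5% of random lists on either side. Of the 132 medians, 11 stand apart, and the darkest squares are the integrated stress response (0.48) and cholesterol synthesis (-0.38) with DDT.

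Across the 6 insecticides, 11 of 132 list medians stood apart, where 1.32 would if the genes within a list varied independently. Genes that share a function can vary together between any libraries, which lists of randomly drawn genes do not reproduce. An excess over 1.32 is thus no evidence of an effect of the insecticides. In direct comparison, the stress response was higher with DDT than with chlorpyrifos, carbaryl, deltamethrin and imidacloprid by medians that each stood apart. Against rotenone the difference of 0.19 did not. Cholesterol synthesis was lower with DDT than with each of the other 5 exposed libraries, by medians of -0.54 to -0.31 that all stood apart. Of the 330 list medians between exposed libraries, 31 stood apart, where 3.3 would by the same reckoning. Lists thus stood apart between exposed libraries at least as often as against control. The libraries of such a pair had different insecticides, so this does not measure variation without exposure. The medians of the stress response and cholesterol synthesis with DDT given above are among the 31.

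Genes shared by all 6 insecticides numbered 15, all higher than in control. Among them were the membrane protease Mmp14 (11.9 FPKM in control and 29.2 to 34.8 in the exposed libraries), the secretory GTPase Sar1a (19.2 and 45.7 to 59.0), the small GTPase Hras (12.6 and 39.7 to 43.5), the tetraspanin Tspan9 (1.92 and 5.32 to 6.99) and Syt1 (3.07 and 11.5 to 14.7). Mzt2, Nipa2, Lgalsl, Dhx29, Smim10l1, Isy1, Pqlc1, Commd6 and Ptrhd1 were also shared, as was Zfp11, which was not listed in control and stood at 1.15 to 1.77 in the others. With another library in the place of control, 10 to 20 genes differed from all 6 others, 20 for carbaryl and 10 for imidacloprid. In each such library 10 to 19 genes lay below all 6 others and 0 to 3 above. The common direction of the 15 genes was thus not particular to control. Shuffling each gene's values over the libraries gave a mean of 13.9, with 6 to 22. That mean is fixed by the counts with each of the 7 libraries as reference, control's 15 among them. Only the range adds to those counts. Between 2 insecticides, 34 to 49 genes passed the threshold the same way, against means of 42.4 to 44.2 in the shuffles, whose highest counts were 54 to 64. The number of genes shared by the insecticides was thus no larger than the common use of 1 control library gives.

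The 8 of 22 astrocyte markers that could be used had list medians of -0.10 to 0.03. Of those without a fold, the lipid carrier Apoe, whose ends disagreed, stood at 15.1 FPKM in control, 31.96 with DDT, 45.1 with rotenone and 24.6 with deltamethrin. The start total of Aldh1l1 was at 28.9 in control, 43.5 with rotenone and 39.9 with carbaryl, and that of the receptor Fgfr3 at 2.42 in control, 4.23 with rotenone and 1.43 with DDT. With rotenone, Gja1 (36.2 against 38.3), Slc4a4 (28.7 against 32.4) and Slc1a3 (90.1 against 90.6) were near control or lower, and the end total of Atp1b2 (36.6 against 26.5) and the larger ends of Clu (16.7 against 13.9) and Cst3 (93.7 against 81.6) were higher. No median of the astrocyte, oligodendrocyte, neuronal or progenitor lists stood apart. The astrocyte genes Aldoc (62.5 against 80.2 FPKM, -0.35) and Glul, the glutamine synthetase (122.5 against 148.5, -0.28), were lower with DDT, and Cbs was higher (54.5 against 41.2, 0.39). Gfap, the filament of mature astrocytes, was at 0.638 in control, 0.678 with DDT, 0.632 with imidacloprid and 0.476 with rotenone, and was not listed with chlorpyrifos, carbaryl or deltamethrin. Aqp4 and S100b, also of mature astrocytes, reached at most 0.466 and 0.304. The glial transcription factor Sox9 was at 21.4 to 24.3 in all 7 libraries and the immature neuron gene Dcx at 22.7 to 27.0. Olig2, of oligodendrocyte precursors, had an end total alone of 109.7 with DDT against 160.6 in control and 154.5 to 169.1 in the others. The myelin gene Mbp was at 1.42 in control and 0.626 to 1.68 in the exposed libraries. Map2, a dendrite gene with a start total alone, was at 149.5 in control and 131.8 to 157.0 in the exposed libraries. Nes, of neural progenitors, had ends that disagreed, and its larger end was at 206 in control and 165.4 to 204.7 in the exposed libraries.

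Of the 16 cholinergic genes listed 2 could be used, and of the 9 sodium channel genes 0, so the values below are of single genes. Acetylcholinesterase (Ache), the target of chlorpyrifos and carbaryl, stood at 1.06 FPKM in control, 1.46 with chlorpyrifos and 0.702 with carbaryl, with a mean under 1. The related enzyme Bche was at 3.26 in control, 3.67 with chlorpyrifos, 3.59 with carbaryl and 1.38 with DDT (-0.84). Nicotinic receptor genes were near control with imidacloprid, at 2.25 against 2.12 for Chrna7, 3.46 against 3.51 for the start total of Chrna4 and 2.97 against 3.08 for the end total of Chrnb2. The sodium channel gene Scn3b had a start total of 6.23 in control, 5.85 with DDT and 7.18 with deltamethrin. The larger end of Scn8a was at 4.86 in control, 3.31 with DDT, 2.86 with deltamethrin and 1.86 with chlorpyrifos.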

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

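The tests with the larger end of every gene, either end total alone and genes with 1 annotated transcript were chosen after the results were seen. Counts below are for chlorpyrifos, DDT, rotenone, carbaryl, deltamethrin and imidacloprid against control, which were 112, 113, 106, 135, 113 and 113. A pseudocount of 0.1 FPKM gave 202, 211, 195, 208, 195 and 186, as it lets low genes pass, and a threshold of 1.5-fold gave 366, 416, 404, 388, 388 and 368. The median of the 6 other libraries as reference, which varies less than 1 library, gave 63, 59, 49, 71, 61 and 58. Rescaling to a common sum, which makes values larger so that the pseudocount weighs less, gave 174 for chlorpyrifos, 186 for DDT, 161 for rotenone and 173 for deltamethrin. A mean of at least 5 FPKM, with fewer genes, left 67 for rotenone. The larger end of every gene, over 10749 genes, gave 383, 367, 350, 386, 344 and 374, and the 494 genes with 1 annotated transcript gave 5, 4, 8, 4, 6 and 5. The 15 genes shared by all 6 became 28 with a pseudocount of 0.1, 46 with the larger end, 24 with the start total and 23 with the end total alone. Of the 11 list medians that stood apart, 5 did so in all 10 alternatives run, none with a change of sign. These were cholesterol synthesis with DDT (-0.41 to -0.36), the integrated stress response with DDT (0.39 to 0.50) and rotenone (0.18 to 0.27), G2 and mitosis with DDT (-0.19 to -0.14) and S phase with rotenone (-0.21 to -0.13). p53 targets with chlorpyrifos stood apart in 3 of 10, and no longer with a pseudocount of 0.1 (0.21), no filter (0.19), at least 5 FPKM (0.21), the median of the others (0.076), random lists not matched on expression (0.19), the start total (0.16) or the end total (0.20). Immediate early genes no longer stood apart without a filter, with medians of 0.29 for rotenone, 0.22 for carbaryl and 0.15 for imidacloprid. With the larger end they were 0.24, 0.19 and 0.15. Against the median of the others they were 0.14 for carbaryl and 0.051 for imidacloprid, and with the end total 0.30 for rotenone and 0.15 for imidacloprid. The integrated stress response with chlorpyrifos was 0.12 at 5 FPKM or more. G2 and mitosis with rotenone was -0.10 against the median of the others and -0.12 with the larger end. Where no construction is named, the cause was not tested. At 5 FPKM or more, immediate early genes had too few members for a median. Another 12 list medians, from 11 lists and comparisons, stood apart under an alternative alone. Of 118 named folds at 2-fold, 115 or more stayed at 2-fold with median-of-ratios scaling, a pseudocount of 0.1, and either end total alone. Either end total was taken over the same 6171 genes, kept because their ends agree and valued by the mean of both ends. That most folds and list medians stayed with either end was thus largely set by the filter. Against the median of the others, 69 of the 118 stayed at 2-fold, 38 were smaller and 11 turned. For the genes of the 11 that turned, most of the other libraries were higher than control. The 11 were Nipa2 with chlorpyrifos (-0.084) and deltamethrin (-0.15), Syt1 with chlorpyrifos (-0.13), rotenone (-0.032) and imidacloprid (-0.019), Mzt2 with rotenone (-0.21) and carbaryl (-0.069), Smim10l1 with carbaryl (-0.34) and imidacloprid (-0.71), and Rsrc1 with deltamethrin (-0.061) and imidacloprid (-0.0845). Rescaling moved the median fold by at most 0.02. Scaling of read counts by TMM was not run, since no read counts were used here. No paired analysis was possible because each group had 1 library. The depth is unknown, so what it limits could not be measured.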

Other observations

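The 3 tests that ask whether the control library alone is odd were chosen after the results were seen, and the tests of transcript length and of annotated transcripts were written before theirs.

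Set against the median of the 6 other libraries, each exposed library had lists that stood apart. DDT had a higher integrated stress response (median 0.39) and unfolded protein response (0.12), with lower cholesterol synthesis (-0.38) and lower genes of G2 and mitosis (-0.14). Rotenone had higher fibroblast genes (0.23), cholesterol synthesis (0.15), immediate early genes (0.22) and integrated stress response (0.18), with lower S phase genes (-0.13). Chlorpyrifos had a higher integrated stress response (0.16), and carbaryl (-0.26) and imidacloprid (-0.16) a lower one. NRF2 targets were higher with deltamethrin (0.12), and genes of G2 and mitosis were higher with imidacloprid (0.13), which had lower ribosomal protein genes (-0.06). Control itself had a lower integrated stress response (-0.21) and lower immediate early genes (-0.28), with higher genes of G2 and mitosis (0.10), and the medians against control in these lists contain that difference. Fabp7, a radial glia gene with a start total alone, stood at 2620 FPKM in control, 2452 with chlorpyrifos, 2521 with imidacloprid, 1398 with DDT, 1295 with deltamethrin, 761.7 with carbaryl and 66.2 with rotenone. The gene did not pass the filter on agreeing ends, so it has no fold, and the cause of these differences was not tested. The 9 progenitor and radial glia markers that could be used had a median of 0.01 with rotenone against control (percentile 47.6).

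The DDT library had higher genes of the integrated stress response and lower genes of cholesterol synthesis than control. If control alone were odd, DDT would match the other exposed libraries, but the stress list stood apart against 4 of 5 of them (medians 0.22 to 0.55, and 0.19 against rotenone, which did not) and the cholesterol list against 5 of 5 (-0.54 to -0.31). A trend of the fold with transcript length also fails, since among random lists matched on length the medians lay at percentiles 100 and 0, and the fold correlated with log2 length at -0.03 across genes. An effect of DDT and a difference of this culture or library unrelated to DDT both stay open, since neither was tested with 1 library per group.

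Single genes differed 2-fold between any 2 libraries in like numbers. A candidate explanation is that the reads of a gene were divided differently among its annotated transcripts from library to library. It predicted a larger share of such genes where annotated transcripts are many, and the share was 12.2 times as high with at least 5 transcripts (12.6%) as with 1 (1.03%). The shares were 12.6% and 0% at 20 FPKM or more, but 16.7% and 9.76% at 1 to 5 FPKM, where genes with 1 transcript have nothing to divide and much of the difference needs another source. How much of any named gene's fold comes from this stays open.

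Immediate early genes had positive medians with all 6 insecticides. A candidate explanation is a control library that is low for this list. Control lay at percentile 0.31 against the median of the 6 others (median -0.28), and 1 of 15 pairs of exposed libraries stood apart. Whether control was low by its handling, or all 6 exposures had a like effect, stays open, since control was a single library.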
